A study of Macaca mulatta with 314 samples.

How the data were processed

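Single cells of 3 sorts were profiled from 3 rhesus macaques (Macaca mulatta) negative for SIV, the simian immunodeficiency virus. The sorts were natural killer (NK) cells, B cells and NKB cells, the submitters' name for B cells that express NK cell receptors. The labels give 77 NK, 78 B and 159 NKB cells, 314 in all, from animals 94-09 (plate 0), 237-09 (plates 1 and 2) and 231-09 (plate 4). Spleen is named as the tissue for animal 94-09 only, and the sort gates and surface markers are not given in the sources used here. Each cell was lysed in its own well, polyadenylated RNA was turned into full-length cDNA with a SMART-Seq kit, and libraries were made with Nextera reagents. This chemistry has no unique molecular identifiers, so PCR copies cannot be told from separate molecules, and intervals and floors below cover counting error only.

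The deposited values are raw read counts per gene symbol, with a column per cell and no normalization by the authors. The submitters' notes name STAR 2.5.2b and Seurat 4.0.4, and the genome build, annotation, read counter and cell filter are not given in the sources used here. The values were checked to be whole numbers with column totals that differ from cell to cell. The table holds 18281 symbols, of which 365 had no reads in any cell, 15272 were found in a table of gene names and 15906 in RefSeq names of a current macaque assembly. Coordinates are therefore not given. Heavy and light chain constant genes, T cell receptor constant genes, KLRC2 and FCGR3A are absent from the table, while JCHAIN appears as IGJ and class II genes carry the prefix MAMU. CD3E held 183 reads over all cells and was not tested.

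Cells of an animal are not independent replicates, so reads were summed over the cells of each sort in each animal, giving 9 sums of 3077455 to 36007677 reads. The design fixed this choice, the gene lists, the rule for named genes and most alternatives before the data were examined. Genes were tested with edgeR 4.0.16 quasi-likelihood fits (TMM factors, filterByExpr, a term for the sort) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, and 11923 genes passed the filter. TMM factors ran from 0.814 to 1.17, and the most abundant gene took at most 5.06% of a sum. Levels are counts scaled to library size (CPM), given as mean ± SD over 3 animals unless another number of sums is stated, and log2 fold changes carry their standard error (SE). Because the same animals gave all 3 sorts, the pairing was checked. Deviations of sums from their sort's mean correlated across genes at 0.0862 to 0.268 for 9 pairs of sums of an animal and at -0.143 to -0.0377 for sums of different animals. A fit with animal as a replicate block was therefore run beside each test. A permutation of 3 animals against 3 cannot give a two-sided p under 0.10, so single values per animal are described without a test.

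Folds against a sort with no reads are lower bounds computed with 3 reads per sum in its place, and where a sort held 1 to 3 reads in all the pooled ratio is given with its counting interval. Named genes are the 10 with the largest log2 fold change in each direction among genes past the threshold, with the same direction in 3 animals and at least 20 CPM in the higher sort. Up to 4 members per gene list with the smallest p were added, and members against the direction of their list. KLRC1, KLRC3, KLRD1, NCR1, FCGR3B, MS4A1, CD79A, CD14, PRF1 and GZMB were always given. Some genes that met these rules are left out of the text. The 25 lists cover NK receptors and signalling, cytotoxic effectors, NK and innate lymphoid transcription factors, the B cell receptor and coreceptors, B cell transcription factors, immunoglobulin chains, MHC class II presentation, and naive, memory, atypical, marginal zone, germinal centre and plasma cell genes. They also cover T cell, innate lymphoid cell, monocyte, dendritic cell, neutrophil and erythroid genes, proliferation, interferon-stimulated genes, cytokines and their receptors, chemokine receptors, toll-like receptors and immediate early genes. Lists were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and p values were adjusted over the lists of a comparison.

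Single cells were clustered in scanpy 1.11.5 on log CPM of 2000 variable genes centred per plate, with 15 principal components, 15 neighbours and Leiden resolution 1. Clusters were named from marker lists fixed beforehand, with 12 B and 12 NK markers among them. A marker counted as detected at 5 reads, and a cell counted as holding a marker set with at least 3 of its markers. Pairs of an NK and a B cell of a plate were added in the computer (800 pairs) as a picture of wells with both cells. Shares of cells carry exact Clopper-Pearson 95% intervals, and a share of 0 carries the upper limit that 3 cells would give. Cells were also thinned to 50000 reads, which 290 cells reached.

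Alternatives were DESeq2 1.42.0 or its size factors, no or a stricter low-count filter, leaving out an animal, a plate or shallow cells, fits of only the 6 sums compared, thinned cells, means over cells with limma, a test against a 2-fold change, leaving out immunoglobulin genes, and other cluster and marker settings. The edgeR fits were tested on simulated data with 200 changed genes. At the spread estimated from these sums (median tagwise dispersion 1.63) edgeR recovered 24% of 16-fold, 12% of 8-fold and 2% of 4-fold changes in NKB versus B, and 12 of its 31 calls (38.7%) were false. In that simulation the fit with an animal block made 8 calls with 0 false, and DESeq2 made 192 calls of which 142 (74.0%) were false.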

Results

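The data are 314 single-cell transcriptomes from 3 macaques, sorted as NK, B or NKB cells, with 39 to 79 NKB cells, 17 to 41 NK cells and 17 to 39 B cells per animal. Median reads per cell were 273868 in NKB, 275545 in NK and 292978 in B cells. Depth differed more between animals than between sorts. The median cell held 175532 reads in animal 231-09, 466949 in 237-09 and 163904 in 94-09. The median number of genes detected was 3334, 3661 and 1296 in the same order, so cells of 94-09 showed the fewest genes. The comparisons ask which NK and which B cell genes NKB cells express beside each of the other sorts.

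NK and B cells, the reference pair, differed in many lineage genes, with 77 genes higher and 0.981% of the 11923 tested genes lower in NK cells (edgeR quasi-likelihood, Benjamini-Hochberg, n = 3 animals per sort). GZMH, which encodes a granzyme of cytotoxic granules, averaged 3911 ± 1607 CPM in NK cells and 0.203 ± 0.178 CPM in B cells (SD), a log2 fold change of 13.88 ± 1.65 (SE, adjusted p = 4.77e-05). PRF1, the pore-forming perforin, averaged 1101 ± 356 and 0.110 ± 0.191 CPM (adjusted p = 9.3e-05). KLRC1, the inhibitory receptor NKG2A, averaged 813 ± 247 and 0.252 ± 0.436 CPM (log2 11.04 ± 1.61, adjusted p = 0.000449). On the B cell side MS4A1, which encodes CD20, averaged 3611 ± 658 CPM against 135.2 ± 55.1 CPM in NK cells (log2 -4.74 ± 0.65, adjusted p = 0.000263). CD79A, a signalling chain of the B cell receptor, averaged 2261 ± 374 against 3.74 ± 4.09 CPM (adjusted p = 0.00048).

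Many named genes of this reference pair had no reads in 1 of the sorts, and for these only a lower bound of the fold is given. CTSW, a cathepsin of cytotoxic lymphocytes, was at least 1066-fold higher in NK cells, GZMM at least 964-fold, PLA2G16 at least 637-fold, SH2D1B at least 378-fold, FASLG at least 286-fold, S1PR5 at least 253-fold and CXCR6 at least 222-fold. FGFBP2 averaged 95.5 ± 57.9 CPM against 0 reads in B cells (adjusted p = 0.0307). GZMK had a log2 fold change of 12.95 ± 1.87. In the other direction CTSH was at least 2149-fold lower in NK cells, FCRLA at least 1030-fold, HHEX at least 627-fold, MILR1 at least 503-fold, LY86 at least 491-fold, C10orf10 at least 424-fold, BTLA at least 358-fold, RAB30 at least 333-fold, TNFRSF13B at least 322-fold and PNOC at least 300-fold. KLRC3 (log2 9.67, adjusted p = 0.00399), NCR1 (8.46, adjusted p = 0.00399) and GZMB (9.20, adjusted p = 0.00197) were higher in NK cells. KLRD1 (log2 6.63, adjusted p = 0.0802), FCGR3B (5.08, adjusted p = 0.179) and CD14, a monocyte marker (1.18, adjusted p = 0.995), did not pass.

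By list, 14 of 25 NK receptor and signalling genes rose in NK cells over B cells (18 adjusted over the list alone, median log2 7.67, or 7.43 with genes lacking reads at their bound, camera adjusted p = 3.72e-22, 0.0309 with an estimated correlation). LILRB1, an inhibitory receptor shared with B cells, was lower only when adjusted over the list alone (log2 -5.83). Of the cytotoxic effectors 12 of 16 rose (14 adjusted over the list alone, median 9.07, or 8.55 with bounds, adjusted p = 1.39e-22, 0.0309 with an estimated correlation). Among NK and innate lymphoid transcription factors ID2 and EOMES rose, 2 of 12 (8 adjusted over the list alone, median 4.05, adjusted p = 1.23e-07, but 0.131 with an estimated correlation), and EOMES did not pass with animal as a block (adjusted p = 0.0751). T cell genes that NK cells also use rose in 4 of 16 cases (among them LAT, TRAT1 and TCF7; 6 adjusted over the list alone, median 3.54; adjusted p = 1.34e-05, 0.132 with an estimated correlation). MKI67, the Ki-67 antigen of cycling cells, was the 1 of 22 proliferation genes to pass (log2 9.01, adjusted p = 0.00151; 3 adjusted over the list alone, with RRM2 and STMN1; list median 1.89, adjusted p = 0.0057, 0.310 with an estimated correlation). None of 21 interferon-stimulated genes passed (OAS1 alone adjusted over the list alone; median 1.01, camera adjusted p = 0.0421, 0.0669 with the block and 0.217 with an estimated correlation).

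B lineage lists fell in NK cells. Of the B cell receptor and coreceptor genes 21 of 27 were lower (26 adjusted over the list alone, median log2 -7.31, camera adjusted p = 3.72e-39, 0.000694 with an estimated correlation), among them CR2, the complement receptor CD21, SWAP70 (-10.40) and CD72 (-11.88). The pooled ratio of B to NK cells for CR2 was 28940 (counting interval 5194 to 1143000), on a single NK read. B cell transcription factors fell in 7 of 12 cases, including SPIB (-9.26), MEF2C (-7.73), EBF1 (-7.83) and BCL11A, at least 224-fold lower (8 adjusted over the list alone, median -7.43, or -6.70 with bounds; adjusted p = 6.85e-17, 0.00131 with an estimated correlation). MHC class II presentation fell in 10 of 12 genes (12 adjusted over the list alone, median -6.99, adjusted p = 1.39e-22, 0.00989 with an estimated correlation), with CD74, the invariant chain, at 219 ± 178 against 17059 ± 8003 CPM. Naive B cell genes fell in 4 of 9 (among them TCL1A, FCER2 and CCR7; 8 adjusted over the list alone, median -3.36; adjusted p = 4.95e-10, 0.00456 with an estimated correlation), marginal zone genes in 3 of 8 (CR2, MZB1, CD1D; 7 adjusted over the list alone, median -7.95; adjusted p = 3.82e-11, 0.0295 with an estimated correlation) and germinal centre genes in 2 of 8 (LMO2, ELL3; 4 adjusted over the list alone, median -4.66, or -3.86 with bounds; adjusted p = 0.00013, 0.0341 with an estimated correlation). IGLL5 and IGJ, 2 of 3 immunoglobulin genes, were lower (2 adjusted over the list alone, median -5.00; adjusted p = 0.000525, 0.0309 with an estimated correlation). Atypical B cell genes fell in 2 of 12 (among them FCRL5; 6 lower and 2 higher, ITGAX and TBX21, adjusted over the list alone; median -4.23, or -3.35 with bounds; adjusted p = 0.0143, 0.135 with an estimated correlation). With animal as a block CD1D (adjusted p = 0.0738) and ELL3 (0.0794) did not pass. With the block and an estimated correlation together, the list calls between NK and B cells were lost for NK receptors (adjusted p = 0.117), cytotoxic effectors (0.101), immunoglobulin genes (0.101) and germinal centre genes (0.117).

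Lists without a call between NK and B cells still held single genes that differed, such as the B cell genes CD86 (log2 -8.23), CD83 (-6.15), CXCR5 and TLR10 and the NK cell gene IL2RB (8.86). The camera adjusted p was 0.403 for memory, 0.152 for plasma cell, 0.913 for innate lymphoid cell, 0.176 for monocyte, 0.978 for dendritic cell, 0.0681 for neutrophil, 0.281 for erythroid, 0.326 for cytokine, 0.382 for chemokine receptor, 0.0936 for toll-like receptor and 0.978 for immediate early genes. Median, mean and test direction differed in sign for memory genes (median 0.66, mean -1.84, tested lower), innate lymphoid cell genes (1.06, -2.08, lower) and chemokine receptors (-0.77, 0.30, lower). Without animal 237-09, which holds most reads, 33 genes were higher and 52 lower in NK cells.

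NKB cells carried the B cell programme that NK cells lacked. In this comparison 89 genes were higher in NKB than in NK cells and 0 lower (edgeR quasi-likelihood, Benjamini-Hochberg, n = 3 animals). MS4A1 averaged 3817 ± 1214 CPM in NKB and 135.2 ± 55.1 CPM in NK cells (log2 4.82 ± 0.66, adjusted p = 0.000284, higher in 3 of 3 animals). CD79A averaged 2748 ± 1179 and 3.74 ± 4.09 CPM (log2 9.58 ± 1.39, adjusted p = 0.000536). For 10 genes with 0 reads in NK cells only a lower bound is given: CTSH was at least 1431-fold higher, FCRLA at least 944-fold, LY86 at least 545-fold, MILR1 at least 516-fold, HHEX at least 467-fold, C10orf10 at least 383-fold, RAB30 at least 368-fold, BTLA at least 248-fold, TTC24 at least 230.0-fold and TNFRSF13B at least 229.7-fold.

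Of the B cell receptor and coreceptor genes 20 of 27 rose in NKB over NK cells (25 adjusted over the list alone, median log2 6.95, camera adjusted p = 1.74e-45, 0.000446 with an estimated correlation), with SWAP70 at 10.21 ± 1.12 and CD72 at 11.38 ± 1.31. MHC class II presentation rose in 9 of 12 genes (12 adjusted over the list alone, median 6.96, adjusted p = 1.67e-25, 0.00885 with an estimated correlation): MAMU-DRB1 averaged 5503 ± 658 against 40.7 ± 35.6 CPM, MAMU-DMA 1804 ± 653 against 7.52 ± 3.13 CPM and CD74 14068 ± 6754 against 219 ± 178 CPM. B cell transcription factors rose in 6 of 12 cases, among them SPIB (9.17), EBF1 (7.87) and MEF2C (7.58) (9 adjusted over the list alone, median 7.20, or 6.12 with bounds; adjusted p = 1.2e-16, 0.00131 with an estimated correlation). IGLL5, an immunoglobulin lambda-like gene, was the 1 of 3 immunoglobulin genes to rise (log2 10.63). Adjusted over the list alone 2 rose, with IGJ. The list had a median of 4.07 (camera adjusted p = 0.00023, 0.0305 with an estimated correlation).

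B cell subset lists were also higher in NKB than in NK cells. Marginal zone genes rose in 2 of 8 cases (CR2 and MZB1; 7 adjusted over the list alone, median log2 6.11; camera adjusted p = 1.82e-11, 0.0274 with an estimated correlation). Naive B cell genes rose in 2 of 9 (FCER2, the receptor CD23, and TCL1A; 4 adjusted over the list alone, among them CCR7; median 1.00; adjusted p = 2.98e-07, 0.00885 with an estimated correlation). Atypical B cell genes rose in 2 of 12 (among them FCRL5 at 9.33; 5 adjusted over the list alone, with ZBTB32, LILRB1 and SOX5; median 2.99; adjusted p = 0.00285, 0.0962 with an estimated correlation), and FCRL5 did not pass with animal as a block (adjusted p = 0.0501). LMO2 was the 1 of 8 germinal centre genes to rise, at least 125.7-fold (3 adjusted over the list alone, with ELL3 and RGS13; median 2.46; adjusted p = 0.0156, 0.0503 with the block and 0.150 with an estimated correlation). With the block and an estimated correlation together, the calls were lost for naive B cell genes (adjusted p = 0.0644) and immunoglobulin genes (0.0777). CD86 (9.01), CXCR5 and TLR10 rose in lists that were not called. Without animal 237-09, 5 lists were called higher, and 36 genes were higher and 1 lower.

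NK genes were lower in NKB than in NK cells in 3 of 3 animals for each of KLRC1, KLRC3, KLRD1, NCR1, PRF1 and GZMB, but none passed the test for single genes. KLRC1 averaged 132.3 ± 142.2 CPM in NKB and 813 ± 247 CPM in NK cells (log2 -2.62 ± 1.10, adjusted p = 0.755), PRF1 156.7 ± 135.5 and 1101 ± 356 CPM (-2.81 ± 1.01, adjusted p = 0.545) and GZMB 2051 ± 2201 and 13507 ± 5629 CPM (-2.72 ± 1.19, adjusted p = 0.786). KLRC3 had log2 -3.39 (adjusted p = 0.689), KLRD1 -2.94 (1.00), NCR1 -3.79 (0.415) and FCGR3B -3.66 (0.723). Across all genes 657 had an unadjusted p under 0.05 in either direction, and DESeq2 called 24 lower, the blocked edgeR fit 3 and the fit on means over cells (limma) 70.

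As lists, NK receptors were lower in NKB cells (0 of 25 called; 10 lower and LILRB1 higher adjusted over the list alone; median log2 -2.53; camera adjusted p = 3.04e-14, 0.0917 with an estimated correlation), as were cytotoxic effectors (0 of 16; 4 adjusted over the list alone, CCL5, GZMH, CCL4 and PRF1; median -2.77; adjusted p = 1.57e-12, 0.0962 with an estimated correlation). NK transcription factors (0 of 12; ID2 adjusted over the list alone; median -1.92; adjusted p = 0.000222, 0.236 with an estimated correlation) and T cell genes (0 of 16; median -2.23; adjusted p = 0.000409, 0.197 with an estimated correlation) were lower too. Proliferation genes (0 of 22; median -2.33; adjusted p = 0.0134, 0.0555 with the block, 0.347 with an estimated correlation) and neutrophil genes (0 of 6; median -1.45; adjusted p = 0.0359, 0.0566 with the block, 0.161 with an estimated correlation) lost their call with the block. The camera adjusted p was 0.279 for memory, 0.0675 for plasma cell, 0.897 for innate lymphoid cell, 0.168 for monocyte, 0.396 for dendritic cell, 0.201 for erythroid, 0.0851 for interferon-stimulated, 0.401 for cytokine, 0.215 for chemokine receptor, 0.0664 for toll-like receptor and 0.985 for immediate early genes. Sums of animal 231-09 held reads of squamous epithelial genes and of S100A8 and S100A9, members of the monocyte list, in all sorts. Those of 94-09 held haemoglobin reads (HBB, of the erythroid list, at 1.91% to 5.06% of reads).

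**Figure D1:**
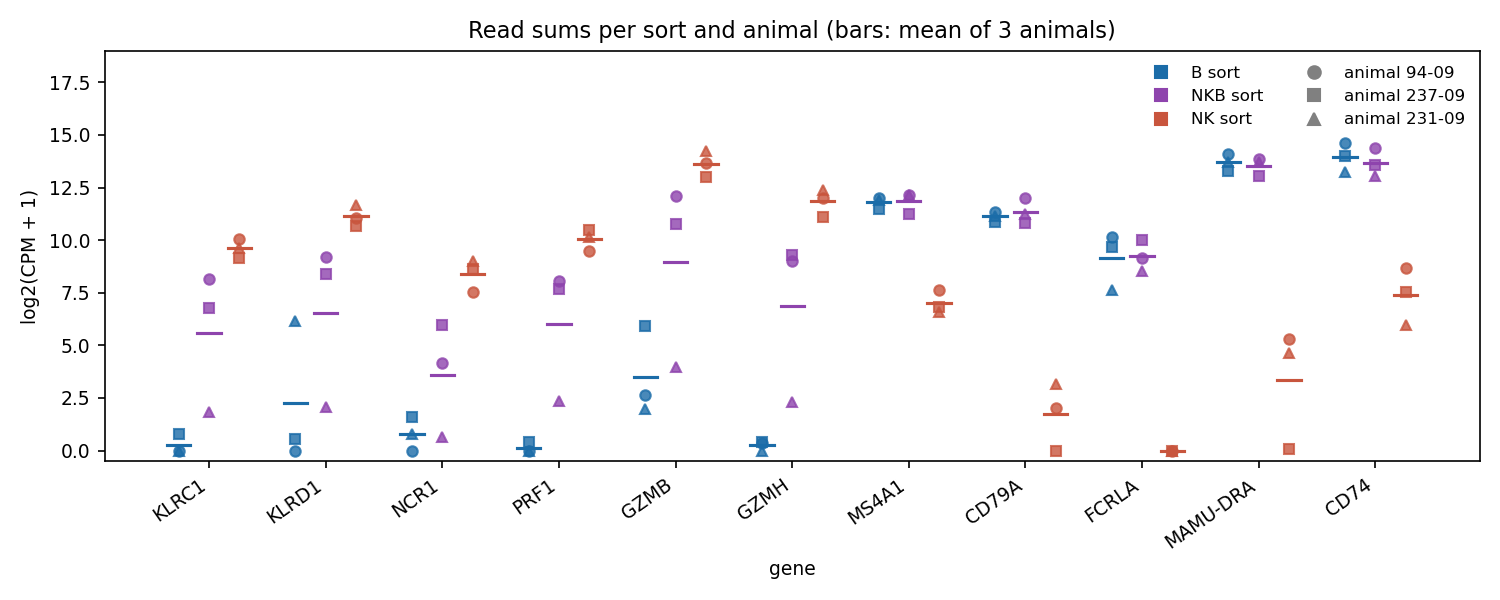
Levels of 11 genes as log2(CPM + 1) in the summed reads of each sort and animal; points are the 3 animals and bars their mean. MS4A1 and CD79A stand at similar levels in NKB and B sums, while KLRC1, PRF1 and GZMB in NKB sums lie between the B and NK sums with a wide spread between animals.

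Beside B cells, NKB cells showed 17 genes that were higher and 0 that were lower (edgeR quasi-likelihood, Benjamini-Hochberg, n = 3 animals), and the higher genes were mainly those of NK cells. GZMH averaged 386 ± 335 CPM in NKB and 0.203 ± 0.178 CPM in B cells (log2 10.53 ± 1.49, adjusted p = 0.00699, higher in 3 of 3 animals). Animal 231-09 added little to these differences. It held 790 of the 194289 NKB reads of the 11 NK receptor and cytotoxic genes called here. It gave 7860216 of the 50802732 NKB reads of all genes. CD247, the zeta signalling chain of NK and T cell receptors, averaged 133.7 ± 118.7 and 0.189 ± 0.327 CPM (8.77 ± 1.26, adjusted p = 0.00699), PRF1 156.7 ± 135.5 and 0.110 ± 0.191 CPM (9.62 ± 1.43, adjusted p = 0.00774) and KLRC1 132.3 ± 142.2 and 0.252 ± 0.436 CPM (8.42 ± 1.47, adjusted p = 0.0232). GNLY, the granule protein granulysin, averaged 2518 ± 3282 and 7.08 ± 5.67 CPM (8.47, adjusted p = 0.0278). Against 0 reads in B cells, CTSW was at least 460.0-fold higher, GZMM at least 113.8-fold, SH2D1B at least 72.1-fold, PLA2G16 at least 66.1-fold and FASLG at least 31.8-fold. The pooled NKB to B ratio was 1248 for LAT (counting interval 223.7 to 49300) and 831.5 for CMA1 (230.0 to 6869). GZMK (10.07) and CD2 (6.38) complete the 13 named genes, and GNLY, TARP, FYB and EFCC1, which fall outside the rule for named genes, were named after their values were seen.

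The calls between NKB and B cells depended on which animals were in the fit. With animal as a block only CD247 passed (adjusted p = 0.00231, 1 gene in all), 0 genes passed without 237-09 and 0 without 94-09, while 37 passed without 231-09. At the level of single tests 235 genes had an unadjusted p under 0.05 and DESeq2 called 57 higher and 3 lower. Without the NKB cells that clustered with NK cells, 0 genes were called (an alternative chosen after seeing the data). Leaving out cells by their NK genes lowers those genes by design. The 11 NK receptor and cytotoxic genes called with all cells went from a median log2 of 10.07 ± 2.40 (SD over genes) to 5.62 ± 1.71.

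B cell identity genes showed no call between NKB and B cells: MS4A1 averaged 3817 ± 1214 and 3611 ± 658 CPM (log2 0.08 ± 0.56) and CD79A 2748 ± 1179 and 2261 ± 374 CPM (0.28 ± 0.95), each with an adjusted p of 1.00. NK genes that missed the threshold were GZMB (log2 6.49 ± 1.42, adjusted p = 0.0993), KLRC3 (6.27, 0.253), NCR1 (4.66, 0.623), KLRD1 (3.69, 1.00) and FCGR3B (1.42, 1.00), and CD14 stood at -2.81.

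Of the NK receptor and signalling genes 4 of 25 rose in NKB over B cells (CD247, KLRC1, CD2 and SH2D1B; 15 adjusted over the list alone, median log2 4.55, or 4.48 with bounds, camera adjusted p = 1.79e-12, but 0.199 with an estimated correlation). Cytotoxic effectors rose in 7 of 16 cases (12 adjusted over the list alone, median 6.56, or 5.74 with bounds, adjusted p = 6.63e-18, 0.190 with an estimated correlation). With animal as a block these counts were 1 and 0. NK transcription factors were higher as a list (0 of 12 called; 4 adjusted over the list alone, EOMES, ID2, ZBTB16 and NFIL3; median 1.74; adjusted p = 0.000895, 0.518 with an estimated correlation), as were T cell genes (1 of 16, LAT; 4 adjusted over the list alone, among them TRAT1 and TCF7; median 1.35, or 1.00 with bounds; adjusted p = 0.00461, 0.518 with an estimated correlation).

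Lower in NKB than in B cells were naive B cell genes (0 of 9 called, 0 adjusted over the list alone, median log2 -0.95; camera adjusted p = 0.00363, 0.190 with an estimated correlation) and germinal centre genes (0 of 8, 0 adjusted over the list alone, median -0.94; adjusted p = 0.00461, 0.199 with an estimated correlation). IL4R, the interleukin-4 receptor, averaged 57.9 ± 9.87 against 198 ± 168 CPM, lower in 3 of 3 animals with an adjusted p of 1.00. Neither list kept a call without 231-09, and without 237-09 1 list was called lower and 2 were called higher. No call was made for the B cell receptor list (median -0.13, adjusted p = 0.281), B cell transcription factors (-0.15, 0.0683), MHC class II presentation (-0.10, 0.281), immunoglobulin genes (0.768), memory (0.937), atypical (0.842), marginal zone (0.103) or plasma cell genes (0.944). The same held for innate lymphoid cell (0.970), monocyte (0.944), dendritic cell (0.342), neutrophil (0.937), erythroid (0.993), proliferation (0.342), interferon-stimulated (0.461), cytokine (0.461), chemokine receptor (0.937), toll-like receptor (0.970) and immediate early genes (0.970).

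The position of NKB cells between the other sorts was measured with genes called on 2 animals and read in the held-out animal, on a scale from 0 (B cells) to 1 (NK cells) of log2 CPM. For genes higher in B cells NKB cells stood at -0.0020, 0.0281 and 0.0299 in animals 231-09, 237-09 and 94-09 (mean 0.0187 ± 0.0179, SD, n = 3). For genes higher in NK cells they stood at 0.101, 0.690 and 0.771 (mean 0.521 ± 0.366). On linear CPM, chosen after seeing the data, the means were 0.147 for NK genes and 0.105 for B genes.

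No gene was higher, and none lower, in NKB than in both NK and B cells (0 and 0 of 11923 by edgeR; 0 and 0 by DESeq2). A gene had to pass both comparisons, while edgeR recovered 24% of 16-fold and 2% of 4-fold simulated changes in NKB versus B. A sum that mixes NK-like and B-like cells also cannot exceed both sorts through the mixing. The count therefore cannot show whether NKB cells have genes of their own.

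**Figure D2:**
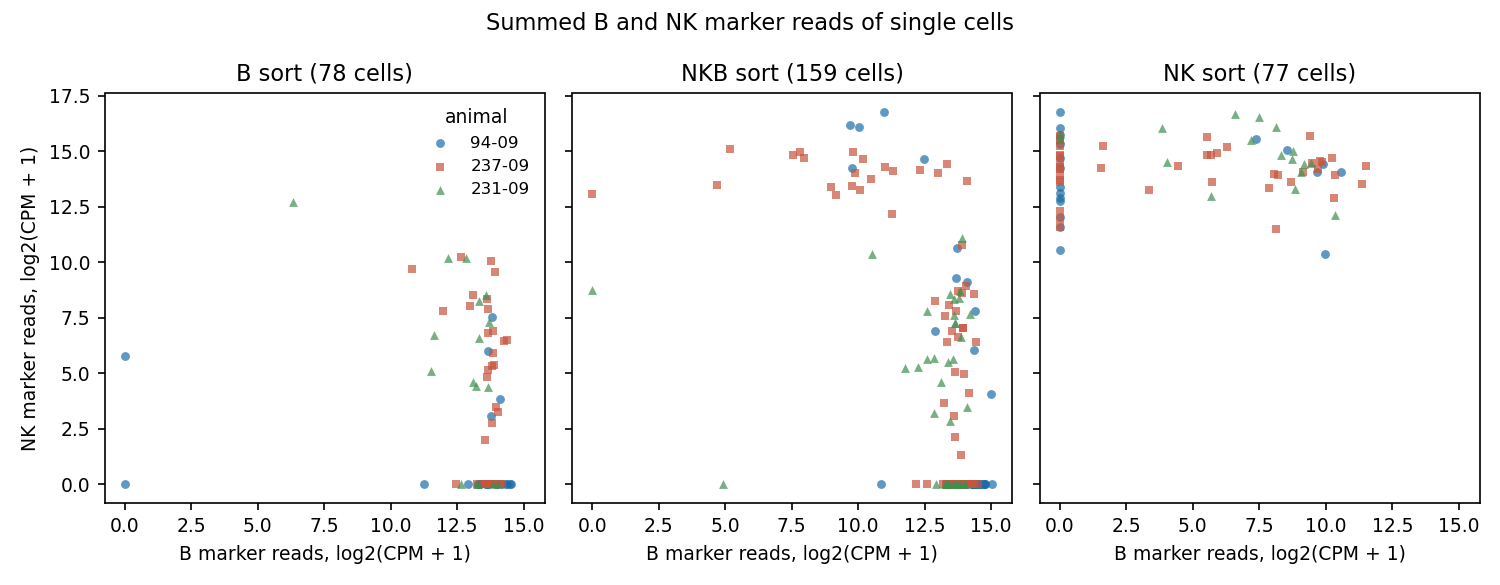
Summed reads of 12 B markers (horizontal) against 12 NK markers (vertical) in each cell, as log2(CPM + 1), in panels for the B, NKB and NK sorts, with a symbol per animal. Most NKB cells lie with the B cells, a minority lies with the NK cells, and 12 NKB cells hold both marker sets.

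Cell by cell, the NKB sort was mixed. Of the NKB cells 72.96% fell into B-like clusters (exact interval 65.4% to 79.7%), with a mean over animals of 73.97% ± 5.75 (SD, n = 3). NK-like clusters held 23 NKB cells (14.5%, 9.40% to 20.9%), with a mean over animals of 11.7% ± 11.4. NK-like clusters were led by GZMB, GNLY, NKG7, GZMH and KLRD1, and MAMU-DRA was among the 10 leading genes of every B-like cluster. CD79A and CD79B were among those of each B-like cluster except cluster 4 (22 cells), which was led by ACP5 and SP140. The NK-like share was 18 of 79 NKB cells in 237-09 (22.8%), 5 of 41 in 94-09 (12.2%) and 0 of 39 in 231-09, which allows a share of up to 7.69%. In the B sort 65 of 78 cells were B-like and 0 NK-like, which allows up to 3.85%, and in the NK sort 68 of 77 were NK-like and 1 B-like. No cluster was named T-like, monocyte-like, plasma cell-like, plasmacytoid dendritic cell-like, neutrophil-like or erythroid-like. A cluster of 41 cells from all sorts, 20 of them NKB, had few reads (median 52358) and no lineage markers among its leading genes, which were long genes such as TTN, MUC16 and NEB, and it was left unnamed. B-like clusters still followed the animals after centring: cluster 7 held 23 of the 28 B-like NKB cells of 231-09 and cluster 3 held 33 of 33 of those of 94-09.

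**Figure D3:**
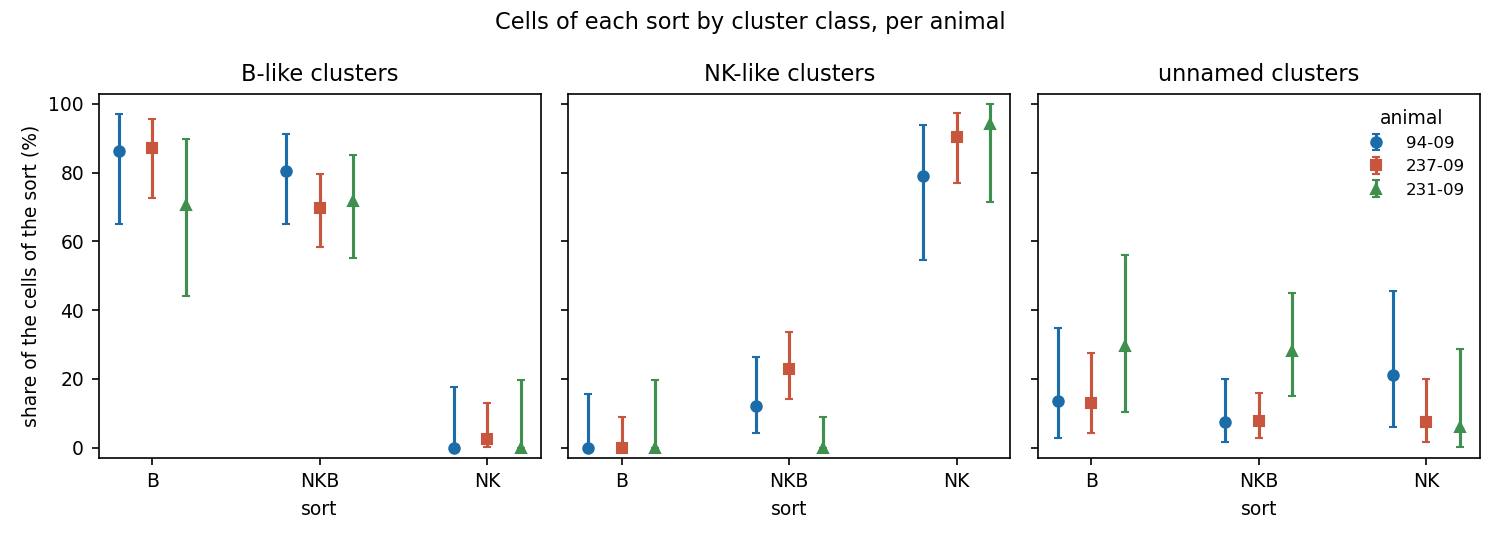
Share of cells in B-like, NK-like and unnamed clusters for each sort and animal, in percent, with exact 95% intervals as error bars. The NK-like share of NKB cells is 0 of 39, 18 of 79 and 5 of 41 cells in animals 231-09, 237-09 and 94-09.

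By marker detection 79.9% of NKB cells held B markers only (exact interval 72.8% to 85.8%), 15 cells held NK markers only and 5 held neither. Both sets were present in 12 NKB cells (7.55%, 3.96% to 12.8%), with a mean over animals of 5.45% ± 7.44 (SD, n = 3). Both sets were present in 2 of 78 B cells (2.56%) and 2 of 77 NK cells (2.60%), and in 735 of 800 simulated NK and B pairs (91.9%). The 12 wells came from 237-09 (11 of 79) and 94-09 (1 of 41), with 0 of 39 in 231-09, which allows up to 7.69%. At an equal depth of 50000 reads 10 NKB cells held both (6.71%). Without 237-09 the mean over animals was 1.22%. In 7 of the 12 wells at least 7 markers of each set were detected, and 9 of the 12 lay in NK-like clusters.

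Within B-like clusters transcripts of the NK receptor genes KLRC1, KLRD1 and NCR1 were rare in both sorts at 5 reads. Surface protein was not measured here, and a transcript below 5 reads does not show that its protein is absent. KLRC1 was detected in 1 B-like NKB cell (0.862%, exact interval 0.0218% to 4.71%) and 2 of 65 B-like B cells (3.08%, 0.375% to 10.7%). KLRD1 was detected in 1 B-like NKB cell and 1 of 65 B cells. NCR1 was detected in 1 B-like NKB cell and 0 of 65 B cells, the latter allowing up to 4.62%. These clusters rest partly on NK genes. In all wells with at least 3 B markers, a choice made after seeing the data, KLRC1 was detected in 11 NKB cells (7.91%, 4.02% to 13.7%) and 2 of 73 B cells (2.74%, 0.334% to 9.55%). KLRD1 was detected there in 12 NKB cells (8.63%) and 2 of 73 B cells, and NCR1 in 11 NKB cells (7.91%) and 1 of 73 B cells. These shares include wells with both marker sets and were not tested. Median depths in the B-like clusters were 274926 and 320189 reads. Between B-like NKB and B-like B cells, summed per animal, edgeR called 0 genes higher and 0 lower of 9710 (95 with an unadjusted p under 0.05, 0.978%; DESeq2 4 higher and 3 lower; n = 3 animals). Naive B cell genes were lower as a list (median log2 -0.95, camera adjusted p = 0.00705, 0.779 with an estimated correlation). Repeated on the wells with at least 3 B markers, the test again called 0 and 0 genes. NK receptors (median 3.05, adjusted p = 0.000488, 0.543 with an estimated correlation) and cytotoxic effectors (3.02, adjusted p = 2.24e-06, 0.435 with an estimated correlation) were higher as lists. The 12 wells with both marker sets held 105596 of the NK marker reads in these wells and the wells with B markers only held 3491. In B-like clusters the same lists had medians of 0.17 and 0.19.

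Within NK-like clusters NKB cells came from 237-09 (18 cells) and 94-09 (5 cells) and were set against NK cells of 3 animals. MAMU-DRA, the class II alpha chain, was the 1 gene higher in NKB cells (1325 ± 1874 CPM in 2 sums against 23.6 ± 22.2 CPM in 3, log2 5.82 ± 1.20, edgeR adjusted p = 0.0157), but not with animal as a block (1.00). The rise in MAMU-DRA came from 237-09 alone, with 2650 CPM in NKB and 0.0536 CPM in NK cells, against 0 and 44.1 CPM in 94-09. With animal as a block CD79B was the 1 gene higher (edgeR adjusted p = 0.00104), though it did not pass without the block. CD79B stood at 531.2 and 646.4 CPM in NKB cells of 237-09 and 94-09, against 0.1608 and 25.81 CPM in their NK cells. MS4A1 was also higher in both animals (941.8 and 521.8 against 109.2 and 206.5 CPM), without a call. CD79A was higher in 237-09 only. Among other B cell genes, MHC class II presentation had a median log2 of 3.78 (5 of 10 adjusted over the list alone, camera adjusted p = 0.121) and B cell receptor genes 1.62 (3 of 12, adjusted p = 0.0611). Of the 23 NKB cells here 9 held both marker sets, 8 of them from 237-09. SPINK5, S100A8 and S100A9, abundant on the plate of 231-09 in every sort, were lower, and that animal gave no NKB cells here. Without 231-09 the counts were 2 higher and 1 lower. Leaving out either other animal leaves a single NKB sum, so that the spread comes from the NK sums alone, and those counts are not read further.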

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

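The linear CPM scale, the sums without haemoglobin genes or without NK-like NKB cells, the wells with at least 3 B markers and leaving out animals for shares and positions were chosen after seeing the data. In NKB versus B, 17 genes were higher and 0 lower. DESeq2 gave 57 and 3, no low-count filter 54 higher, at least 20 CPM in 3 sums 4, the replicate block 1, only the 6 sums compared 1, without plate 1 of 237-09 8, thinned cells 10, limma on means over cells 0 and sums without NK-like cells 0. The 13 named genes among those calls kept their direction in every setting where they had a value, and 1 kept its call with the replicate block. The other comparisons are given as percent of the genes tested, with the same denominator for every alternative. For NKB versus NK, 0.746% higher and 0% lower, DESeq2 gave 2.13% and 0.201%, no filter 1.17% and 0.226%, limma 0.302% and 0.587%, and the replicate block 0.0252% lower. For NK versus B, 0.646% higher and 0.981% lower, DESeq2 gave 2.51% and 3.25%, no filter 1.27% and 1.62%, and limma 0.973% and 0.428%. Leaving out 1 animal gave 0 to 37 genes higher in NKB than B, 0.302% to 0.822% higher and 0% to 0.0168% lower in NKB than NK, and 0.277% to 0.621% higher and 0.436% to 1.01% lower in NK than B.

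Gene lists called with an estimated correlation were 0 higher and 0 lower in NKB versus B (4 and 2 with the preset), 0 lower in NKB versus NK (6) and 2 higher in NK versus B (6). Leaving out 1 animal gave 2 to 4 lists higher and 0 to 3 lower in NKB versus B and 5 to 8 higher in NKB versus NK. With the replicate block the germinal centre, proliferation and neutrophil lists lost their call in NKB versus NK, and the interferon-stimulated list lost its call in NK versus B. With the block and an estimated correlation together, the NK receptor, cytotoxic, immunoglobulin and germinal centre lists in NK versus B and the naive and immunoglobulin lists in NKB versus NK also lost the call they held with the estimated correlation alone. Among named genes of these comparisons EOMES, CD1D, ELL3 and FCRL5 lost their call with it, and so did MAMU-DRA within NK-like clusters. Position on linear CPM was 0.147 for NK genes and 0.105 for B genes, and on means over cells 0.1565 for NK genes and 0.0386 for B genes, against 0.521 and 0.0187. The mean share of B-like NKB cells was 84.6% without plate centring and 88.03% in cells with at least 50000 reads, in both of which no cluster stayed unnamed. At 2 markers of each set 13.9% of NKB cells held both, as a mean over animals, against 9.30% of B and 14.5% of NK cells. NKB cells thus did not stand above NK cells at that cut. At a read minimum of 1 the means were 8.44% in NKB, 7.34% in B and 3.59% in NK cells. At 5 markers of each set they were 2.95%, 0.855% and 0.813%. Within NK-like clusters leaving out 1 animal gave 0.0210% to 0.147% of genes higher and 0.0105% to 1.33% lower, but the upper ends come from fits with a single NKB sum. The cause of these shifts was not tested except where fewer cells or genes entered. No named gene changed direction, while with limma the larger count passed from higher to lower genes in NKB versus NK and from lower to higher genes in NK versus B. At the spread between these 3 animals most simulated changes between NKB and B cells were not recovered, with 24% called at 16-fold, 12% at 8-fold and 2% at 4-fold.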

Other observations

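The detection shares, the sources of NK reads by cluster, the 7 wells with many markers of each set, the comparison with a pair in every well, the plate 4 test and the splits within B-like clusters were chosen only after the results were seen. Among cells of B-like clusters, FGR, a SRC-family kinase, was detected at 5 reads in 20 NKB cells (17.2%, exact interval 10.9% to 25.4%) and 1 of 65 B cells (1.54%, 0.0389% to 8.28%). The NKB share was 6 of 28 cells in 231-09, 4 of 55 in 237-09 and 10 of 33 in 94-09, against 0 of 12, 1 of 34 and 0 of 19 B cells, and at an equal 50000 reads it was 13.0% (7.49% to 20.6%) against 0 of 63 B cells, which allows up to 4.76%. FGR averaged 116.4 ± 155.9 CPM in sums of B-like NKB cells and 0.476 ± 0.824 CPM in those of B-like B cells (log2 7.58, SD, n = 3), and did not pass edgeR's Benjamini-Hochberg threshold (adjusted p = 1.00). FGR had the smallest unadjusted p of the 9710 genes tested there (edgeR p = 0.00087). Its shares come from the same cells and give no separate support. CD2, an adhesion receptor of NK and T cells, was detected in 12 NKB cells (10.3%), 7 of them from 231-09, and 1 of 65 B cells, and at 50000 reads in 5.22% of NKB cells and 1 of 63 B cells. ITGAX, the integrin CD11c, is in the atypical B cell list but was higher in NK than in B cells when adjusted over that list alone. ITGAX was detected in 25 NKB cells (21.6%) and 7 of 65 B cells, and at 50000 reads in 14.8% and 9.52%. TBX21 of the same list was detected in 8.62% and 6.15% at all reads. The list was not called within B-like clusters (camera adjusted p = 0.910). By animal ITGAX was detected in 9 of 28 NKB and 0 of 12 B cells of 231-09, 11 of 55 and 7 of 34 of 237-09, and 5 of 33 and 0 of 19 of 94-09.

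Naive B cell genes were also counted cell by cell in B-like NKB and B-like B cells, at median depths of 274926 and 320189 reads. TCL1A was detected in 26.7% of the NKB and 44.6% of the B cells, CCR7 in 31.0% and 44.6%, IL4R in 27.6% and 40.0%, and FCER2 in 55.2% and 69.2%. BTG1 of the same list was not lower (96.6% and 95.4%). The mean CPM of FCER2 over cells was higher in NKB than in B cells in 231-09 (179.1 against 103.2) and 94-09 (432.4 against 366.3). It was lower in 237-09 (385.1 against 472.1). At an equal 50000 reads TCL1A was detected in 26.1% and 41.3%. CD27, a memory marker, was detected in 42.2% and 38.5%. These shares pool cells of 3 animals and were not tested.

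NK genes that were higher in NKB than in B sums may come mostly from a minority of wells that cluster with NK cells. Those 23 wells held 95.6% of the NK marker reads of the NKB sort, while B-like NKB cells held 1.30% of them. This speaks against an even low spread over all wells as the main source of the pooled reads. The clusters were named with the same markers, so these 2 shares are partly fixed as well. For 231-09, without NK-like NKB cells, they say nothing on a low spread. B-like NKB cells held 0.601% of the reads of the called NK genes. Because the clusters rest partly on NK genes, that low share is partly fixed by the clustering. It cannot show whether cells with a B programme were the main source. By marker state, the 12 wells with both marker sets held 37.1% of the NK marker reads. The 15 wells with NK markers only held 61.6%. Of the 23 NK-like wells 9 held both marker sets. A pair of cells in every well is also argued against, as both marker sets were seen in 7.55% of NKB cells and 91.9% of simulated pairs. Whether B-like NKB cells raise these genes at a low level stays open: only CD247, GNLY and CD2 could be tested there, with a median log2 fold change of 4.90 ± 2.97 (SD), against 1.27 ± 2.27 over 12 genes chosen by unadjusted p and 0.17 ± 2.26 over all 19 NK genes testable there. In 231-09, which had no NK-like NKB cell, the 1067 NK marker reads lay 84.7% in B-like cells, and whether the NK-like wells reflect the gates or a state of NKB cells was not tested.

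Wells with both marker sets could each hold an NK and a B cell. Their genes detected, relative to the other NKB wells of the plate, had a median ratio of 1.38, near the lower end of the 5th to 95th percentile range of medians of simulated pairs (1.35 to 1.59, median 1.465). Reads spilling between wells cannot be told apart from this, since the weaker marker set stood at a median of 17.6% of its level in wells with a single set, between the bounds set for either outcome. That level was not measured in the simulated pairs, which mix the 2 cells in equal parts, so it was not weighed against a pair. The 12 wells were not alike. Their weaker set ran from 4.66% to 69.5% and their genes ratio from 0.867 to 1.74. Over all 12 wells the median level was 19.5% for B markers and 97.4% for NK markers. In 5 of the 12 only 3 or 4 markers of the set with fewer markers were detected. In the 7 wells with at least 7 markers of each set, which were picked for a strong weaker set, the median levels were 55.1% for B and 68.6% for NK markers and the genes ratio was 1.44, which does not settle it for the 12 wells. These medians are taken per marker set and are not comparable with the 17.6%. The weaker set of these 7 wells ran from 14.2% to 69.5%. A single cell with both programmes would give such wells too and was not tested.

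Squamous epithelial genes marked every well of plate 4. At least 3 of KRT13, KRT4, SPRR3, CSTA, SPINK5, EMP1, CNFN and CRNN were detected in 100% of B, NK and NKB wells of that plate and in 0 wells of the others, and they took 0.632% to 0.853% of its reads. S100A8 averaged 4063 CPM and S100A9 2757 CPM there. This is consistent with RNA of epithelial origin shared by the wells of the plate. Plate 4 is also the only plate of 231-09, so animal and plate cannot be separated, and no biological explanation was tested.

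Splits of the 6 sums compared number 10, too few for a share under 0.05. The real split called 17 genes in NKB versus B and the highest other 3, 89 and 0 in NKB versus NK, and 194 and 0 in NK versus B, so that in each 1 of 10 splits reached the real count. Within B-like clusters the real split called 0 genes and the highest other 0, and 10 of 10 reached it. Any split reaches a count of 0, so this result was fixed and says nothing on whether the sorts differ there.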
